A study of Mus musculus with 12 samples.

How the data were processed

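Gene expression was measured by RNA sequencing in 12 libraries of ATDC5 cells, a mouse cell line that the labels call wild-type cartilage progenitor cells and that is widely used as a culture model of chondrocyte differentiation. Per the labels, cells were grown at 37 °C in high-sugar medium with serum and then held for 10 min at 37 °C, 40 °C or 44 °C. Each temperature had 4 biological replicates per the series design text, and the samples carry the numbers 1 to 4 within each group. The time between the end of the exposure and RNA extraction is not stated, so the values belong to an unknown interval after heating. Total RNA was extracted with a TRIzol-based purification kit, polyadenylated RNA was captured on poly-T beads, and fragmented RNA was primed with random hexamers, per the labels' protocols.

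The deposited values are raw counts per gene, 1 column per sample, with replicates not pooled. Per the submitters' processing notes, fastp, HISAT2 2.0.5, StringTie 1.3.3b and featureCounts 1.5.0-p3 were used with the mouse build mm10. The notes give neither the role nor the order of these tools. Whether counting used the strand is not stated, so reads of overlapping or antisense genes cannot be told apart, and the handling of reads that map to several places is not stated either. Genes with near-identical copies, such as Hspa1a and Hspa1b, are therefore reported as uncertain, since counting could have split their reads. Gene symbols, identifiers, biotypes and coordinates are those of the deposited table.

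The deposited counts summed to between 16269026 and 19506705 per library. A limit of 3 counts, the upper bound that a count of 0 allows, corresponded to between 0.154 and 0.184 CPM (counts scaled to the library total) and covers counting error only. The table held 54532 genes, of which 28743 had at least 1 read in some library. No entry lacked a gene name. Replicates of each group were compared with a chi-square statistic per gene, which lay between 2.88 and 21.4 for the 18 pairs of libraries within groups, so no library was a copy of another of its group and each was counted as 1 replicate.

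Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14424 genes and between 99.86% and 99.9% of the counts of each library. Library sizes were scaled by TMM (trimmed mean of M values). A quasi-likelihood model with 1 mean per temperature was fitted to all 12 libraries, so that the 3 groups shared 1 estimate of the spread. The 3 pairwise contrasts and a joint test over the 3 temperatures were made with two-sided quasi-likelihood F-tests. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the log2 fold change divided by the square root of its F statistic. The common biological coefficient of variation was 0.102. CPM values of single genes are given as mean ± SD over the 4 libraries of a group on TMM-scaled library sizes. Summed CPM of lists, and the losses in CPM of interferon genes, were taken on library totals without TMM.

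Gene lists were fixed together with the tests, the alternatives and the rule for named genes before the data were examined. There were 41 lists with 804 symbols, covering stress responses, cartilage and matrix, growth, the cell cycle, metabolism and markers of other cell types. Of the symbols, 787 matched a gene name in the table, 12 matched by an older symbol and 5 had no match or an ambiguous one. The 37 lists with at least 5 genes past the filter were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The test used a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 37 lists. The test was repeated with the correlation between genes estimated from the data for each list, and with fry, which tests each list without reference to other genes. Each list also has a count of its called members, adjusted over all genes and adjusted over the list alone.

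The rule for named genes took, per comparison, the 6 called genes with the highest and the 6 with the lowest log2 fold change. They had to have a mean of at least 5 CPM in the higher group, no overlap between the groups, and no predicted-gene or pseudogene name. It also took the 3 members with the smallest p of each of the 6 lists with the smallest camera p. The genes Hspa1a, Hspa1b, Hsph1, Dnajb1, Hspa8, Cirbp, Rbm3, Fos, Atf3, Cdkn1a, Mki67, Sox9, Col2a1, Acan and Runx2 were named in every comparison. Counts of called members are given for lists called by camera, and for those of cartilage matrix, hypertrophy, growth signalling and other cell types whatever their call. Other genes named in the text were chosen after their values were seen, and this is said where they appear. A few genes that the rule took are not reported here, although they stay in all counts of genes and lists.

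The comparisons of 40 °C and 44 °C against 37 °C share the 37 °C libraries. Overlap, covariance and correlation between them were therefore set beside 20 simulations of unchanged groups against the same libraries, and beside the 6 ways of giving 2 of the 37 °C libraries to each comparison. The simulations drew each gene independently and so hold no differences between libraries that many genes share.

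The gene test was checked on simulated counts drawn from the means and depths of these libraries, with 100 genes changed 1.5-fold, 100 changed 2-fold and the 20 genes of the endoplasmic reticulum list changed 0.8-fold among 14424 genes. For 44 °C against 37 °C it recovered 54% of the 1.5-fold and 74% of the 2-fold changes in the right direction and called 5 of 14204 unchanged genes. For 40 °C against 37 °C it recovered 58% and 84% and called 14 unchanged genes, and for 44 °C against 40 °C it recovered 62% and 79% and called 7. Genes were drawn independently, so differences between libraries that many genes share were absent. These rates do not cover errors from such differences.

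The alternatives tried were DESeq2 1.42.0 and limma voom as tools, DESeq2 size factors or library totals as scaling, no filter or a filter of at least 5 CPM in 4 libraries, and robust dispersion estimates. A threshold of 0.01, a fit of only the 8 libraries compared, the replicate number as a block, an estimated correlation or fry for lists, and each library left out in turn were tried as well. A further alternative, chosen after seeing the data, added to the model a within-group axis of the libraries, the first component of their deviations from their group means. For a list, counts and ranges over alternatives cover up to 16 camera refits at the preset correlation. These refits used DESeq2 size factors, the filter of at least 5 CPM in 4 libraries, the block, the axis or each library left out. The estimated correlation and fry are not among them and are given apart. Reads were not reprocessed, and no reference sequence was used except for the GC content of genes in the closing section.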

Results

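The series asked how temperature affects the growth of chondrocytes, the cells of cartilage. It compared mRNA levels after 10 min at 40 °C or 44 °C with those at the culture temperature of 37 °C. The data were deposited gene counts from 12 libraries of mouse ATDC5 cells, 4 each at 37 °C, 40 °C and 44 °C. Total counts lay between 16469745 and 19506705 at 37 °C, 16269026 and 19303450 at 40 °C and 16606597 and 17612087 at 44 °C. Protein-coding genes took 97.3% ± 0.0206 of counts at 37 °C, 97.5% ± 0.11 at 40 °C and 97.5% ± 0.0591 at 44 °C (mean ± SD, n = 4 each). Mitochondrially encoded genes took 2.01% ± 0.164, 1.92% ± 0.166 and 1.90% ± 0.0925. The first 2 principal components held 28.8% and 13.5% of the variance, and libraries of the 3 temperatures overlapped on the first. Coordinates below are on mm10, as the deposited table gives them.

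**Figure D1:**
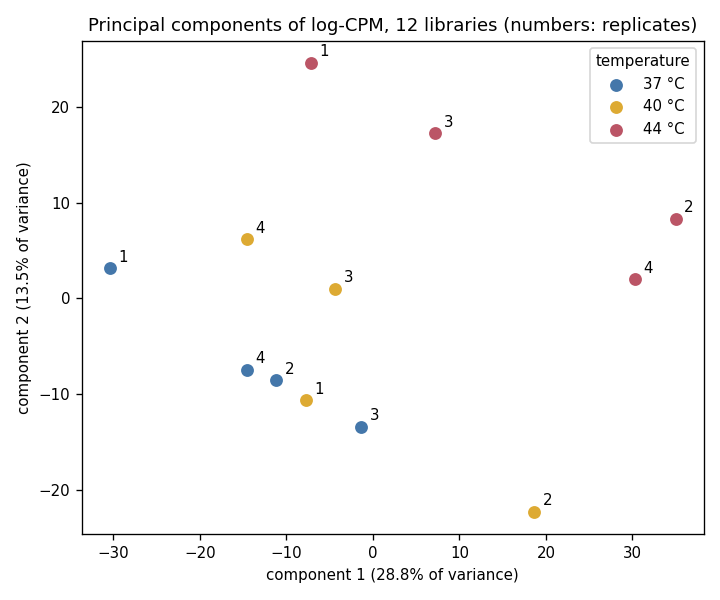
Principal components of the 12 libraries, computed on log2 CPM. The horizontal axis is the first component (28.8% of the variance) and the vertical axis the second (13.5%), each point is a library and colours mark the 3 temperatures. The 44 °C libraries spread from −7.10 to 34.98 on the first component, and 40 °C replicate 2, at 18.6, lies among them on that axis.

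Libraries also differed within their groups along a common axis, the first component of their deviations from the group means, which held 29.8% of the within-group variance. On it 44 °C replicate 2 (1.5), 40 °C replicate 2 (1.46) and 44 °C replicate 4 (1.37) lay high and 37 °C replicate 1 (−1.47) and 44 °C replicate 1 (−1.07) low. The group means were −0.424 ± 0.78 at 37 °C, 0.012 ± 1.02 at 40 °C and 0.412 ± 1.24 at 44 °C (SD, n = 4 each). The means of 28 of the 37 gene lists tested followed this axis, built without the genes of each list, within groups (exact permutation within groups, Benjamini-Hochberg adjusted), 8 rising and 20 falling along it. Ribosome biogenesis genes rose along it over the 12 libraries, with Pearson r = 0.996 (permutation p = 0.000145, adjusted p = 0.000892). Spearman's rho was 0.986 (permutation p = 0.000217), and r was 0.993 without the 2 libraries farthest out. Interferon response genes fell along it, with r = −0.924 (permutation p = 7.23e-05, the smallest the permutations can give, adjusted p = 0.000892). Their rho was −0.930 (permutation p = 0.000145), and r was −0.939 without the 2 farthest. Genes of the endoplasmic reticulum unfolded protein response had r = −0.330 (permutation p = 0.333, adjusted p = 0.385), rho = −0.287 (permutation p = 0.431) and r = −0.0605 without the 2 farthest. That list was the only one of the 11 called below for 44 °C against 37 °C whose mean did not pass this test by Pearson's r. By Spearman's rho the list of the NRF2 oxidative stress response did not pass either (rho = −0.573, adjusted p = 0.0943, against r = −0.703, adjusted p = 0.0395).

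After 10 min at 44 °C, a few inducible heat shock genes rose while most of the other cytosolic chaperone genes on the list did not pass the test. Hspb1, which encodes the small heat shock protein HSP27 (ENSMUSG00000004951, protein coding, chromosome 5, 135887919 to 135889563), rose 3.10-fold, from 71.3 ± 7.77 CPM at 37 °C to 221 ± 22.8 CPM at 44 °C. Its log2 fold change of 1.63 ± 0.092 (SE) had an adjusted p of 2.94e-07. Hspa1b, an inducible HSP70 gene (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), rose from 8.68 ± 0.336 to 18.8 ± 1.21 CPM (log2 fold change 1.12 ± 0.089, adjusted p = 6.56e-06). Its near-identical neighbour Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) rose from 0.776 ± 0.207 to 4.61 ± 1.33 CPM (2.57 ± 0.27, adjusted p = 7.51e-05), and the division of reads between the 2 genes is uncertain. All 4 libraries at 44 °C lay above all 4 at 37 °C for each of these 3 genes.

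Other chaperone genes of the same list gave small values. Hsph1, an HSP110 chaperone gene, had 209 ± 34.3 CPM at 37 °C and 209.6 ± 46.9 CPM at 44 °C (log2 fold change 0.00, adjusted p = 0.993). The co-chaperone gene Dnajb1 had 0.03 (adjusted p = 0.718), and the constitutive HSP70 gene Hspa8 had −0.15 (adjusted p = 0.339). With the within-group axis as a covariate, Hsph1 (−0.23, adjusted p = 0.00123, range over its alternatives 0.00123 to 1) and Hspa8 (−0.28, adjusted p = 1.89e-06, range 1.89e-06 to 0.678) passed the test as lower. Of 31 measured heat shock genes, 5 rose and 3 fell over all genes tested, and also adjusted over the list alone. The other 5 called members were chosen after their values were seen. Cryab, a small heat shock protein gene (0.50), and Hsf1, the gene of the main heat shock transcription factor (0.26), rose. The small heat shock protein gene Hspb8 (−0.37), its partner Bag3 (−0.30) and the co-chaperone gene Dnajb4 (−0.28) fell. The list did not pass camera (adjusted p = 0.141). In this 44C vs 37C comparison it passed as higher without 37 °C replicate 3 (adjusted p = 0.0395, range over its alternatives 0.0395 to 0.88) and without 44 °C replicate 1 (0.0453). Fry for change in either direction gave the heat shock list an adjusted p of 1.59e-10, and called 25 of the 37 lists in this comparison.

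Across all genes, 1975 of 14424 tested were called for 44 °C against 37 °C, 949 higher and 1026 lower, with a median absolute log2 fold change of 0.35. A change of at least 2-fold was seen in 109 of them, 22 higher and 87 lower. The groups did not overlap for 2561 genes (17.8% of those tested), where chance gives 2.86%. Outside the heat shock genes, the matricellular genes Cyr61 and Ctgf, which encode secreted growth regulators of the CCN family, were among the largest increases. Cyr61 (chromosome 3, 145646976 to 145649981) rose from 206 ± 10.4 to 426 ± 28.4 CPM (1.05 ± 0.094, adjusted p = 1.6e-05). Ctgf rose from 19.4 ± 1.12 to 36.9 ± 2.22 CPM (0.93 ± 0.17, adjusted p = 0.00284). The largest decreases by the naming rule were in Dbp, a clock-controlled transcription factor gene (−1.89 ± 0.33, adjusted p = 0.00245), and the antiviral gene Oas2 (−1.79). Next came the macrophage perforin family gene Mpeg1 (−1.52), the secreted glycoprotein gene Lgals3bp (−1.40), the blood cell adaptor gene Fyb (−1.39) and Irf7, an interferon regulatory factor gene (−1.37). Their adjusted p lay between 3.84e-05 and 0.00768. With library totals in place of TMM 2008 were called, 1096 higher and 912 lower. The within-group axis as a covariate gave 3146, and a threshold of 0.01 gave 630. The count of genes called depended on the libraries: it was 3355 without 44 °C replicate 1, 979 without 37 °C replicate 1, 1156 without 37 °C replicate 2 and 1063 without 37 °C replicate 4. It was 980 without 44 °C replicate 2 and 1062 without 44 °C replicate 4.

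**Figure D2:**
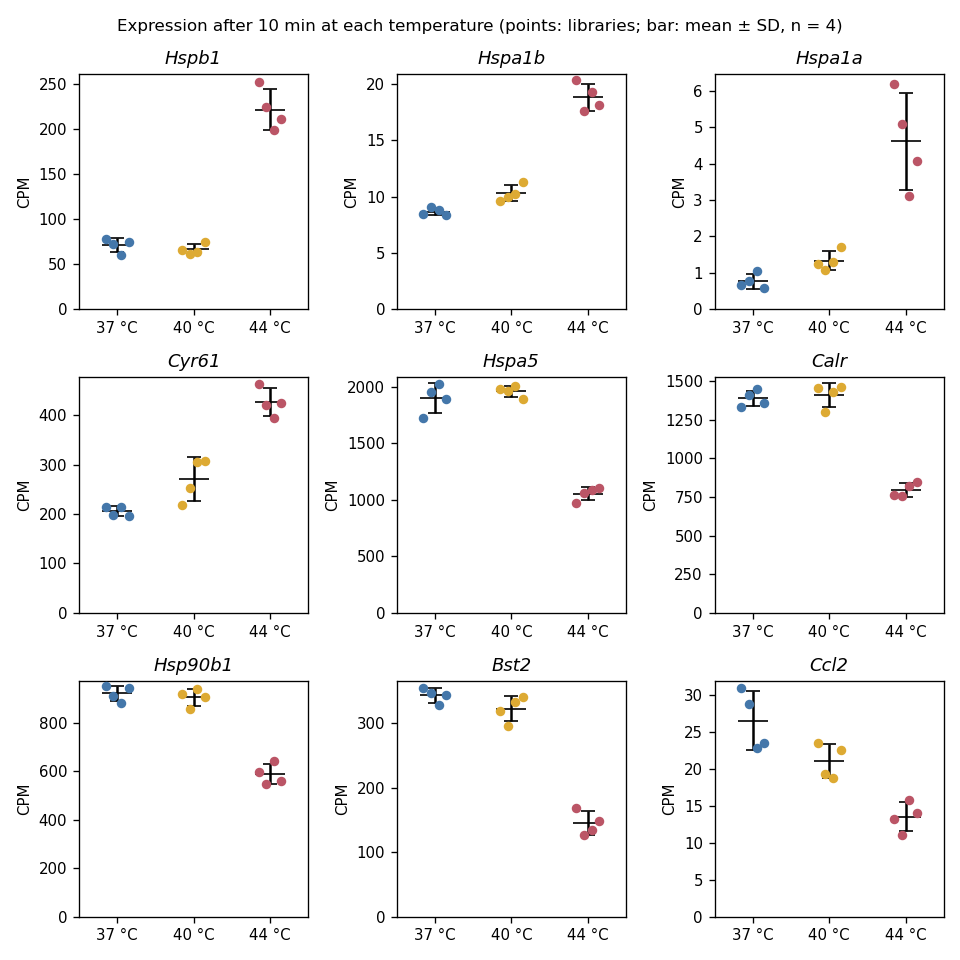
Expression of 9 genes at each temperature. The horizontal axis is the temperature of the 10 min exposure and the vertical axis CPM, each point is a library, and bars show the mean with SD (n = 4). Hspb1, Hspa1b, Hspa1a and Cyr61 are higher and Hspa5, Calr, Hsp90b1, Bst2 and Ccl2 lower at 44 °C than at 37 °C, as for Hspa5 at 1057 against 1903 CPM.

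Genes of the endoplasmic reticulum (ER) unfolded protein response, which encode the folding machinery of the secretory pathway, fell at 44 °C. Hspa5, the gene of the ER chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), fell from 1903 ± 131 to 1057 ± 57.7 CPM (log2 fold change −0.85 ± 0.055, adjusted p = 7.05e-07). Calr, which encodes the calcium-binding chaperone calreticulin (chromosome 8, 84841850 to 84846934), fell from 1388 ± 50.3 to 798 ± 45 CPM (−0.80 ± 0.053, adjusted p = 7.85e-07). Hsp90b1, the ER HSP90 gene (chromosome 10, 86690209 to 86705509), fell from 923 ± 31.7 to 589 ± 42.3 CPM (−0.65 ± 0.054, adjusted p = 8.53e-06). In all, 13 of 20 measured members fell and none rose, and 17 fell adjusted over the list alone, with a median of −0.41. The list passed camera (adjusted p = 1e-15), and it was the only list of 37 called with an estimated correlation (adjusted p = 0.00496 with an estimated correlation). The within-group axis as a covariate ended that call (adjusted p = 0.0683 with an estimated correlation) and left the median at −0.399.

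Interferon response genes, which encode antiviral effectors and their regulators, were also lower. Bst2, which encodes tetherin (chromosome 8, 71534255 to 71537456), fell from 343 ± 11.2 to 145 ± 18.5 CPM (log2 fold change −1.25 ± 0.077, adjusted p = 5.9e-07). Gbp3, a guanylate-binding protein gene, fell from 51.8 ± 2.83 to 26.6 ± 6.27 CPM (−0.96 ± 0.12, adjusted p = 0.000314), and Irf7 fell from 73.4 ± 12.1 to 28.4 ± 10.9 CPM. Of 22 measured members 12 fell and none rose, over all genes and adjusted over the list alone, with a median of −0.49. Camera gave an adjusted p of 3.53e-08, and an adjusted p = 0.694 with an estimated correlation. Their median was −0.319 with the within-group axis, which this list followed, as a covariate. Among NF-kB and inflammatory genes, 10 of 19 fell and 1 rose, and 11 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000356, and adjusted p = 0.694 with an estimated correlation). The cytokine signalling inhibitor gene Socs3 (−0.89 ± 0.083, adjusted p = 2.75e-05) and the chemokine gene Ccl2 (−0.97 ± 0.13, adjusted p = 0.000395) fell. The prostaglandin synthase gene Ptgs2 was the member that rose (0.75 ± 0.071, adjusted p = 2.8e-05).

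Genes of ribosome biogenesis, which make and assemble ribosomal RNA, were higher at 44 °C, with 6 of 24 measured members called over all genes and 19 adjusted over the list alone, all 19 higher. Utp4, a small-subunit processome gene, rose from 138 ± 21.5 to 212 ± 43.2 CPM (log2 fold change 0.63 ± 0.15, adjusted p = 0.0148). Its call was lost without 37 °C replicate 1 (adjusted p = 0.0535) and without 44 °C replicate 2 (adjusted p = 0.055, range over its alternatives 3.52e-07 to 0.055). The list passed camera (adjusted p = 6.44e-06, median 0.44), with an adjusted p = 0.694 with an estimated correlation. Its median was 0.184 with the within-group axis, which this list followed, as a covariate. DNA replication genes were higher too, with 9 of 28 called and 14 adjusted over the list alone, none lower (adjusted p = 7.47e-05, and adjusted p = 0.694 with an estimated correlation). Examples were the DNA primase gene Prim1 (0.55 ± 0.098, adjusted p = 0.00271) and the ribonucleotide reductase gene Rrm1 (0.23 ± 0.041, adjusted p = 0.00273).

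Fibrillar matrix and matrix turnover genes fell in 9 of 23 cases and rose in 2. Adjusted over the list alone, 14 fell and 2 rose (camera adjusted p = 0.000692, and adjusted p = 0.694 with an estimated correlation). The collagen gene Col3a1 fell from 75.8 ± 8.91 to 31.5 ± 9.25 CPM (log2 fold change −1.27 ± 0.17, adjusted p = 0.00051) and the metalloproteinase inhibitor gene Timp2 fell (−0.41 ± 0.064, adjusted p = 0.00136). The matrix glycoprotein gene Tnc rose (0.72 ± 0.11, adjusted p = 0.00105), as did the metalloproteinase gene Mmp3, named in this contrast after its values were seen. Circadian clock genes fell in 8 of 16 cases and rose in 1, the clock activator gene Arntl, named after its values were seen. Of these genes 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000692, and adjusted p = 0.694 with an estimated correlation). NRF2 oxidative stress genes fell in 8 of 20 cases (9 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.000787, and adjusted p = 0.106 with an estimated correlation).

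The remaining 3 lists called had larger camera adjusted p than those above. Cholesterol biosynthesis genes had a median of 0.12 with 5 of 23 higher and 11 higher adjusted over the list alone (camera adjusted p = 0.00252, and adjusted p = 0.694 with an estimated correlation). Among them, chosen after their values were seen, were the enzyme genes Mvk, Idi1 and Cyp51. TRiC chaperonin and prefoldin genes, which fold newly made cytoskeletal proteins, had a median of 0.19. In that list Cct2, Cct4, Cct5, Cct8 and Pfdn4 rose and Pfdn1 fell, of 14 measured, all named after their values were seen, and 8 rose and 1 fell adjusted over the list alone. Camera gave an adjusted p of 0.0251 for it, and an adjusted p = 0.694 with an estimated correlation. In this 44C vs 37C comparison its camera call was lost without 37 °C replicate 1 (adjusted p = 0.0778) and without 44 °C replicate 3 (0.054). It was also lost without 44 °C replicate 4 (0.125, range over its alternatives 0.00261 to 0.125). Glycolysis and hypoxia genes had a median of −0.26. Of 23, the glycolytic enzyme genes Eno1 and Pkm fell, named after their values were seen, or 1 adjusted over the list alone (adjusted p = 0.00451, and adjusted p = 0.698 with an estimated correlation). The glycolysis median was −0.0833 with the within-group axis as a covariate, and its camera call was lost (adjusted p = 0.0775, range over its alternatives 0.000544 to 0.0775).

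**Figure D3:**
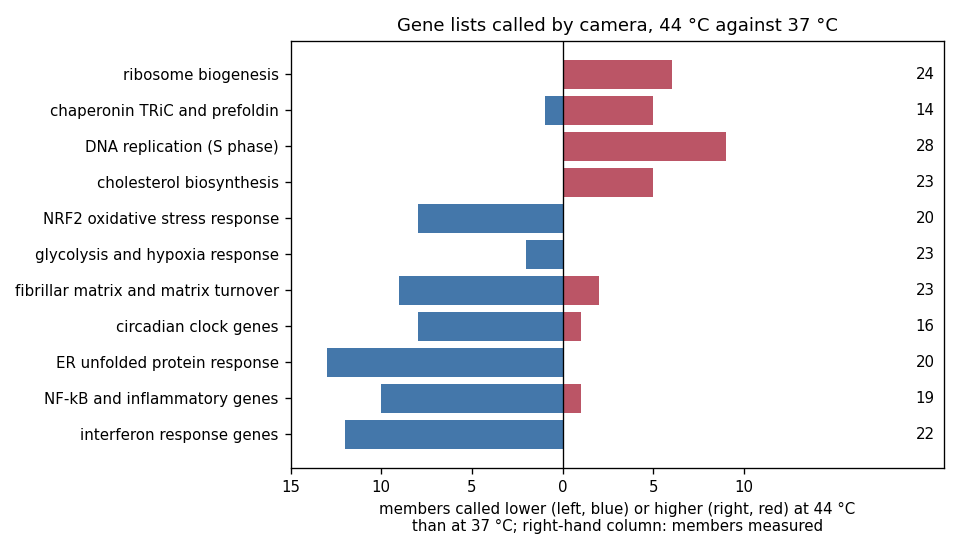
Members called in the 11 gene lists that passed camera for 44 °C against 37 °C. The horizontal axis is the number of members called over all genes, lower to the left in blue and higher to the right in red, and the right column gives the number measured. The ER list has 13 of 20 members lower and none higher, and the ribosome biogenesis list 6 of 24 higher and none lower.

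Genes that mark chondrocyte identity and maturation mostly did not pass the test at 44 °C, as held for all genes tested, of which 13.7% were called. The chondrogenic regulator gene Sox9 had 54.2 ± 10.2 CPM at 37 °C and 48.2 ± 14.9 CPM at 44 °C (log2 fold change −0.17, adjusted p = 0.604). The hypertrophy regulator gene Runx2 had 62.9 ± 3.43 and 60.5 ± 2.46 CPM (−0.06, adjusted p = 0.528). The cartilage matrix genes Col2a1 (0.05, adjusted p = 0.949) and Acan (−0.42, adjusted p = 0.332) had low levels, at 1.21 ± 0.23 and 2.13 ± 0.42 CPM at 37 °C. Of 10 measured cartilage matrix genes only the lubricin gene Prg4 fell (−0.86, list adjusted p = 0.141). Of 12 hypertrophy genes Spp1 (osteopontin, −0.51) and Mef2d (−0.24) fell (list adjusted p = 0.176), as did 2 of 19 growth signalling genes, Igfbp4 (−0.42) and the hedgehog receptor gene Ptch1 (−0.26, list adjusted p = 0.141). These 5 genes were chosen after their values were seen, and the counts were 1, 2 and 2 lower adjusted over the lists alone as well. In this 44C vs 37C comparison the cartilage matrix list passed without 44 °C replicate 1 (adjusted p = 0.047, range over its alternatives 0.047 to 0.534). The proliferation marker gene Mki67 had 741 ± 32.2 and 814 ± 26.9 CPM (0.14, adjusted p = 0.0671). It passed without 44 °C replicate 1 (adjusted p = 0.048), with DESeq2 (adjusted p = 0.0286) and with the within-group axis as a covariate (adjusted p = 0.0139, range over its alternatives 0.0139 to 0.162).

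Further genes fixed beforehand also stayed short of the threshold for 44 °C against 37 °C. The cold-inducible RNA-binding protein genes Cirbp (−0.27, adjusted p = 0.264) and Rbm3 (−0.13, adjusted p = 0.247) were not called. The immediate early gene Fos (0.20, adjusted p = 0.431), the stress transcription factor gene Atf3 (0.17, adjusted p = 0.62) and the cell cycle inhibitor gene Cdkn1a (0.21, adjusted p = 0.498) were not called. Cirbp passed without 44 °C replicate 1 (−0.43, adjusted p = 0.0485, range over its alternatives 0.0485 to 0.551). With the within-group axis as a covariate Rbm3 (−0.21, adjusted p = 0.000651, range 0.000651 to 0.453) and Cdkn1a (0.46, adjusted p = 2.1e-05, range 2.1e-05 to 0.793) passed.

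Markers of other cell types showed no common direction. Of the smooth muscle and perivascular genes, Acta2 (−0.76), Pdgfrb (−0.78) and Cspg4 (log2 fold change −0.30) fell of 5 measured (3 fell and 1 rose adjusted over the list alone, list adjusted p = 0.0823). The summed CPM of that list was 411 ± 16 at 37 °C, 428 ± 45.6 at 40 °C and 344 ± 34.6 at 44 °C. Of the endothelial genes, Pecam1 (0.835 to 1.85 CPM) and Cdh5 (1.26) rose of 5 measured (2 adjusted over the list alone, list adjusted p = 0.0793). Of 6 epithelial genes Krt14 fell (−0.49), with 1 rising and 1 falling adjusted over the list alone. The camera direction of that list was lower (list adjusted p = 0.993) while its median (0.19) and mean (0.06) lay above 0. These 6 genes were chosen after their values were seen. In this 44C vs 37C comparison the smooth muscle list passed without 44 °C replicate 1 (0.0354, range over its alternatives 0.0354 to 0.349). The endothelial list passed without 37 °C replicate 2 (0.0461) and without 44 °C replicate 2 (0.0415, range 0.0415 to 0.13). None of 5 adipocyte (list adjusted p = 0.986) and none of 5 neural genes (list adjusted p = 0.975) was called over all genes or adjusted over the lists alone. The muscle list had 2 measured members and the immune and pluripotent lists 1 each, too few for camera. Their summed CPM at 37 °C and 44 °C were 48.2 ± 5.54 and 48.8 ± 5.06 for muscle, 31.8 ± 6.14 and 24.3 ± 5.64 for immune, and 93.3 ± 3.19 and 94.1 ± 5.1 for pluripotent genes.

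Between 40 °C and 37 °C no gene passed the edgeR test. The genes given here were taken by the naming rule, not as the strongest of all genes. Hspa1b had 10.3 ± 0.704 CPM at 40 °C and 8.68 ± 0.336 at 37 °C (log2 fold change 0.25 ± 0.091), and Hspa1a had 1.33 ± 0.268 and 0.776 ± 0.207 CPM (0.79 ± 0.30). Dnajb1 (0.16 ± 0.052) had a value above 0. The period clock gene Per2 had −0.47 ± 0.17, with 8.86 ± 1.36 CPM at 40 °C and 12.2 ± 0.746 at 37 °C. The unadjusted edgeR p of these 4 genes lay between 0.00866 and 0.0185. Each had an adjusted p of 0.823, the smallest of all 14424 genes but a tie that does not rank them. Hsph1 (unadjusted p = 0.183) and Hspa8 (0.233) shared it. All 4 had no overlap between the 4 libraries at 40 °C and the 4 at 37 °C, as did 553 genes in all (3.83%, where chance gives 2.86%).

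The count of 0 genes from edgeR stood beside 752 genes at an unadjusted p under 0.05, where 721.2 are predicted with no effect. Limma voom also called 0 genes and DESeq2 called 4, all lower. These 4, chosen after their values were seen, were the nuclear-retained noncoding RNA Malat1 (−0.54, DESeq2 adjusted p = 0.0363), the metallothionein gene Mt2 (−0.65, 0.0363), 9230116N13Rik (−1.36, 0.0363) and 3110039I08Rik (−0.50, 0.0453). Without 44 °C replicate 1 a single gene, the pseudogene Gm11585, was called (1.26, adjusted p = 0.0242), chosen for the same reason. With no filter on low counts 13 genes were called, and with the within-group axis as a covariate 11. Values of the genes fixed beforehand were 0.22 for Hsph1, 0.12 for Hspa8, −0.41 for Cirbp, −0.06 for Rbm3, 0.04 for Fos, −0.21 for Atf3, 0.03 for Cdkn1a and 0.09 for Mki67. They were −0.09 for Sox9, −0.26 for Col2a1, −0.37 for Acan and 0.01 for Runx2, with adjusted p between 0.823 and 0.979.

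As groups, ribosome biogenesis, cholesterol biosynthesis and heat shock genes were higher and circadian clock genes lower at 40 °C than at 37 °C by camera. None of the 4 lists was called with an estimated correlation (adjusted p = 0.93 with an estimated correlation for each), and fry called 0 of the 37 lists. No member of these 4 lists was called over all genes or adjusted over the list alone. Ribosome biogenesis had a median of 0.21 over 24 genes (adjusted p = 6.47e-05), with Rrp9 at 0.34, Bop1 at 0.27 and Pes1 at 0.18. Cholesterol biosynthesis had a median of 0.08 over 23 genes (adjusted p = 0.00116), with Mvk at 0.23 and Cyp51 at 0.20. Heat shock genes had a median of 0.12 over 31 genes (adjusted p = 0.00117), and circadian genes −0.24 over 16 genes (adjusted p = 0.00796), with Nr1d2 at −0.15 and Ciart at −0.39. All 4 lists followed the within-group axis, on which 40 °C replicate 2 lay at 1.46. Ribosome biogenesis (r = 0.996) and heat shock genes (r = 0.924) rose along it. Circadian (r = −0.978) and cholesterol biosynthesis genes (r = −0.771) fell along it, the latter against their direction at 40 °C.

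In the 40C vs 37C comparison each of these list calls was lost with at least 1 single library left out. Each was kept in 14 or 15 of 16 camera refits at the preset correlation, which leave out the estimated correlation and fry. Without 40 °C replicate 2 the adjusted p was 0.0838 for ribosome biogenesis (range over its alternatives 3.38e-08 to 0.0838), 0.0648 for heat shock genes (range 0.000357 to 0.0648) and 0.0874 for circadian genes (range 0.000804 to 0.0874). The medians were then 0.0788, 0.0558 and −0.164. Over the alternatives they lay between 0.0788 and 0.301 for ribosome biogenesis, 0.0528 and 0.151 for heat shock genes, −0.298 and −0.143 for circadian genes and 0.0577 and 0.125 for cholesterol biosynthesis. Circadian genes also lost the call without 37 °C replicate 1 (0.0717), and cholesterol biosynthesis genes lost it without 40 °C replicate 4 (0.0622, range 2.55e-06 to 0.0622). The number of lists called was 2 without 40 °C replicate 2, 9 without 37 °C replicate 3, 9 without 40 °C replicate 3 and 10 without 40 °C replicate 4.

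Lists of cartilage matrix (10 measured, adjusted p = 0.487), hypertrophy (12, adjusted p = 0.469), and growth signalling (19, adjusted p = 0.92) had no member called over all genes for 40 °C against 37 °C. Nor had those of adipocyte, endothelial, epithelial, neural and smooth muscle markers (adjusted p = 0.827, 0.136, 0.827, 0.136 and 0.469). Adjusted over the list alone, 1 smooth muscle gene was higher and none of the others was called. For growth signalling the camera direction was higher while the median (−0.01) and mean (−0.02) lay below 0. For smooth muscle it was higher with a median of −0.01 and a mean of 0.05, and for epithelium it was lower with a median of −0.07 and a mean of 0.00.

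Set against 40 °C in place of 37 °C, the 44 °C libraries again had higher Hspb1 and lower ER chaperone and interferon response genes. Hspb1 was 3.33-fold higher (log2 fold change 1.74 ± 0.092, adjusted p = 1.31e-07), with 66.4 ± 6.05 CPM at 40 °C. Hspa1b (0.87 ± 0.088, adjusted p = 6.67e-05) and Hspa1a (1.78 ± 0.25, adjusted p = 0.00106) rose as well. Other large increases were in Mmp3 (0.94 ± 0.14), the syntenin family gene Sdcbp2 (0.93 ± 0.13), the giant muscle protein gene Ttn (0.89 ± 0.15) and the immunoglobulin superfamily gene Igsf9b (0.72 ± 0.13), with adjusted p between 0.00103 and 0.00512. The largest decreases by the naming rule were in Oas2 (−1.56), Lgals3bp (−1.38), Irf7 (−1.28), Col3a1 (−1.20), Bst2 (log2 fold change −1.155) and the calcium-binding protein gene S100a4 (−1.14), with adjusted p between 8.31e-07 and 0.00459.

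For this contrast 724 genes were called, 271 higher and 453 lower, with a median absolute log2 fold change of 0.35. A change of at least 2-fold was seen in 28 of them, 8 higher and 20 lower, and the groups did not overlap for 1546 genes (10.7%, where chance gives 2.86%). With library totals in place of TMM 751 were called, of which 52.7% were higher (396 against 355) in place of 37.4%. DESeq2 called 1220, a fit of the 8 libraries alone called 334, and the within-group axis as a covariate gave 2535. The count was 394 without 40 °C replicate 1, 421 without 40 °C replicate 3, and 420 without 40 °C replicate 4. It was 1265 without 44 °C replicate 1, 426 without 44 °C replicate 2 and 456 without 44 °C replicate 4.

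Of 20 measured ER genes, 14 fell between 40 °C and 44 °C and 19 fell adjusted over the list alone. Among them were Hspa5 (−0.89 ± 0.055, adjusted p = 5.31e-07), Calr (−0.82 ± 0.053, adjusted p = 6.87e-07) and Hsp90b1 (−0.62 ± 0.054, adjusted p = 1.69e-05). The list had a median of −0.40 (camera adjusted p = 2.12e-22) and was the only list called with an estimated correlation (adjusted p = 0.00126 with an estimated correlation). Interferon response genes fell in 9 of 22 cases and in 14 adjusted over the list alone, with a median of −0.42 (adjusted p = 5.72e-11, and adjusted p = 0.679 with an estimated correlation). Examples were Gbp3 (−1.01 ± 0.12, adjusted p = 0.000485) and the viral RNA sensor gene Ddx58 (−0.57 ± 0.087, adjusted p = 0.0019). NF-kB genes fell in 8 of 19 cases and rose in 1, Ptgs2 (0.58 ± 0.071, adjusted p = 0.00052). In that list 8 fell and 2 rose adjusted over the list alone (adjusted p = 0.000811, and adjusted p = 0.679 with an estimated correlation). Socs3 (−0.69 ± 0.083, adjusted p = 0.000471) and the adhesion gene Vcam1 (−0.79 ± 0.13, adjusted p = 0.00206) were among the lower ones.

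Fibrillar matrix genes fell in 7 of 23 cases and rose in 2, Tnc and Mmp3, Tnc having been chosen after its values were seen. Adjusted over the list alone, 14 fell and 2 rose (adjusted p = 7.18e-05, and adjusted p = 0.694 with an estimated correlation). The collagen gene Col5a2 fell by 0.68 ± 0.10 on the log2 scale (adjusted p = 0.00152). NRF2 genes fell in 5 of 20 cases, namely the cystine transporter gene Slc7a11 (−0.72 ± 0.11, adjusted p = 0.00163), the redox genes Srxn1 (−0.30 ± 0.053, adjusted p = 0.00446) and G6pdx (−0.37 ± 0.05, adjusted p = 0.000856), Nqo1 and Pgd. The ferritin gene Ftl1 rose. The last 3 were chosen after their values were seen, and 10 fell and 2 rose adjusted over the list alone (adjusted p = 0.000246, and adjusted p = 0.0556 with an estimated correlation). DNA replication genes rose in 5 of 28 cases, among them Prim1 (0.49 ± 0.098), the chromatin assembly gene Chaf1b (0.37 ± 0.067), Cdc45 and Rrm1, the last 2 chosen after their values were seen. Adjusted over the list alone 8 rose and 2 fell (adjusted p = 0.000623, and adjusted p = 0.694 with an estimated correlation).

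A further 4 lists had weaker calls in this 44C vs 40C comparison. Ribosome biogenesis genes had a median of 0.20 with 0 of 24 called over all genes or adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.841 with an estimated correlation). Circadian genes had Tef lower and Arntl higher of 16 (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0164, and adjusted p = 0.735 with an estimated correlation). Smooth muscle markers had Acta2 (−1.03) and Pdgfrb (−0.77) lower of 5 (3 lower adjusted over the list alone, adjusted p = 0.0164, and adjusted p = 0.679 with an estimated correlation). Glycolysis genes had Pkm lower of 23 (2 lower adjusted over the list alone, adjusted p = 0.0291, and adjusted p = 0.841 with an estimated correlation). These 5 genes were chosen after their values were seen. Without 40 °C replicate 4, where the count of lists called went from 10 to 6, the adjusted p was 0.153 for ribosome biogenesis, 0.0617 for circadian genes, 0.0569 for smooth muscle markers and 0.296 for glycolysis. Ribosome biogenesis was also lost without 40 °C replicate 3 (0.0506), 44 °C replicate 2 (0.275) or 44 °C replicate 4 (0.21). Glycolysis was lost without 40 °C replicate 3 (0.0506), 44 °C replicate 2 (0.281) or 44 °C replicate 4 (0.21). Circadian genes were lost without 44 °C replicate 2 (0.108) or 44 °C replicate 4 (0.0824), and smooth muscle markers were lost without 44 °C replicate 4 (0.0579) or with the within-group axis as a covariate (0.094).

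Heat shock genes as a list did not pass between 40 °C and 44 °C (adjusted p = 0.84), with a camera direction of lower, a median of −0.05 and a mean of 0.09. Of 31 members, Hspa1a, Hspa1b, Hspb1 and Cryab rose and Hspb8 and Bag3 fell, with 4 rising and 3 falling adjusted over the list alone, Cryab, Hspb8 and Bag3 having been chosen after their values were seen. Hspa8 (−0.27, adjusted p = 0.138) passed with no filter on low counts (adjusted p = 0.00985) and with the within-group axis as a covariate (adjusted p = 7.32e-08, range over its alternatives 7.32e-08 to 0.256).

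The other genes fixed beforehand were not called for 44 °C against 40 °C. Log2 fold changes were −0.22 for Hsph1 (adjusted p = 0.475), −0.13 for Dnajb1 (0.189), 0.14 for Cirbp (0.691), −0.07 for Rbm3 (0.647), 0.16 for Fos (0.632) and 0.38 for Atf3 (0.347). They were 0.18 for Cdkn1a (0.654), 0.05 for Mki67 (0.64), −0.08 for Sox9 (0.872), 0.30 for Col2a1 (0.706), −0.05 for Acan (0.947) and −0.07 for Runx2 (0.539). With the within-group axis as a covariate Hsph1 (−0.34, adjusted p = 1.25e-05, range over its alternatives 1.25e-05 to 0.758) and Dnajb1 (−0.13, adjusted p = 0.0436, range 0.0436 to 0.399) passed as lower. Cdkn1a (0.31, adjusted p = 0.0011, range 0.0011 to 0.915) passed as higher.

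Among the lists given whatever their call, cartilage matrix (10 measured, adjusted p = 0.259) and hypertrophy genes (12 measured, adjusted p = 0.299) had no member called over all genes, and 1 lower, and 1 higher and 3 lower, adjusted over the lists alone. Among 19 growth signalling genes Igfbp4 and Ptch1 fell (3 adjusted over the list alone, adjusted p = 0.0742). In this 44C vs 40C comparison that list passed with at least 5 CPM in 4 libraries (0.0393), without 40 °C replicate 2 (0.00716, range over its alternatives 0.00716 to 0.199) and without 44 °C replicate 1 (0.0282). Among epithelial markers Krt18 rose of 6 (1 rose and 1 fell adjusted over the list alone, adjusted p = 0.918). None of 5 endothelial (adjusted p = 0.227), 5 adipocyte (adjusted p = 0.875) or 5 neural markers (adjusted p = 0.391) was called over all genes, with 1 adipocyte gene higher adjusted over the list alone. Igfbp4, Ptch1 and Krt18 were chosen after their values were seen.

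Across the 3 temperatures jointly, 1184 of 14424 genes differed, of which 1138 were also called for 44 °C against 37 °C. The count was 742 without 37 °C replicate 1, 698 without 37 °C replicate 2, and 678 without 37 °C replicate 4. It was 2125 without 44 °C replicate 1, 562 without 44 °C replicate 2, 725 without 44 °C replicate 3 and 609 without 44 °C replicate 4. No gene was called in the same direction at both 40 °C and 44 °C against 37 °C, since edgeR called 0 genes at 40 °C. There 752 had an unadjusted p under 0.05, limma voom called 0 and DESeq2 called 4. Simulated unchanged groups gave 0.05 such genes on average, and independent lists would give 0.

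The log2 fold changes at 40 °C and at 44 °C, both against the same 37 °C libraries, had a covariance across genes of 0.0396, where simulated unchanged groups gave 0.0195 (0.018 to 0.0205 over 20 simulations). The spread of the simulations is too narrow for real libraries, since random regroupings of the 12 libraries gave up to 0.0731. With at least 5 CPM in 4 libraries the observed covariance was 0.0205, but no unchanged groups were simulated for that smaller set of genes. Over all genes tested, the correlation of the log2 fold changes was 0.547 against 0.494 simulated, and 72.5% of genes had the same sign against 66.5% simulated. Genes are not independent replicates, so no p is given for these values. With the 37 °C libraries divided between the comparisons, the covariance was 0.0194 on average (0.0133 to 0.0227 over 6 assignments), the correlation 0.21 and the share with the same sign 62.8%. Dividing the libraries takes out the part that shared libraries give. The 0.0194 is therefore not to be set beside the simulated 0.0195, which holds only that part. The observed covariance less the simulated one was 0.02. Without 37 °C replicate 3 the covariance was 0.0598.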

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

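Of the tests in this part, those with the within-group axis as a covariate use an axis found in the data, and the test for exchanged labels was chosen after the result was seen. In 12 of 222 groups of 4 libraries, a single library stood apart from the other 3, by a gap to the nearest that exceeded Dixon's 95% critical value as a share of the whole range. Chance gives about 1 in 20 such groups, or 11.1 of 222. The measures covered 66 genes and the make-up of the libraries.

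In the 37 °C group, Vcam1 stood apart in replicate 1 (26.7 CPM against 22.6 to 22.8, gap 0.954 of the range), Atf3 in replicate 3 (1.89 against 3.46 to 3.76 CPM, 0.839) and Fos in replicate 4 (2.39 against 3.08 to 3.22 CPM, 0.831). In the 40 °C group, replicate 1 stood apart for the cytokine gene Il6 (59.2 against 38.5 to 40.8 CPM, 0.888), Fyb (5.54 against 3.42 to 3.77 CPM, 0.838) and Gbp3 (55.6 against 52.4 to 52.9 CPM, 0.848). Replicate 2 of that group stood apart for the ribosome biogenesis gene Nop14 (112.8 against 80.3 to 81.8 CPM, 0.952) and for Prim1 (102.5 against 76.1 to 79.9 CPM, 0.854). In the 44 °C group, Ttn stood apart in replicate 3 (4.92 against 5.54 to 5.65 CPM, 0.859). Replicate 4 stood apart for Igsf9b (10.1 against 11.4 to 11.6 CPM, 0.844) and for Fos (3.03 against 3.50 to 3.58 CPM, 0.857). Its share of counts in protein-coding genes also stood apart (97.37% against 97.48% to 97.5%, 0.846).

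Genes of the ER unfolded protein response were lower at 44 °C than at 37 °C, with a median log2 fold change of −0.41 over 20 genes. With the within-group axis, built without the list's genes, as a covariate the median was −0.399 (SD of 12 leave-one-out values 0.0113), which kept 96.4% of its size with 20 of 20 members called lower, and this argues against the axis as the whole cause. The adjusted p with an estimated correlation was then 0.0683 in place of 0.00496, as the estimated correlation was 0.203 in place of 0.0591. Of 10000 random sets matched on GC content, length and expression, 0 had a median as low (central 95% of sets −0.05 to 0.13), which argues against those properties. An effect of the 44 °C exposure on these mRNAs is a candidate explanation and remains a hypothesis. The list was fixed beforehand, but its fall and the tests of its causes rest on the same libraries, and no other data were used.

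Interferon response genes were lower (median −0.49) and ribosome biogenesis genes higher (median 0.44) at 44 °C than at 37 °C, and both lists followed the within-group axis. With the axis as a covariate the interferon median was −0.319 (leave-one-out SD 0.052), 64.7% of its size, which argues against the axis as the whole cause but leaves room for it as a part, with an adjusted p of 0.333 with an estimated correlation. RNA of immune cells is argued against as the whole cause, because the 13 immune genes summed to 31.8 ± 6.14 CPM at 37 °C (24.3 ± 5.64 at 44 °C) while the interferon genes lost 416 CPM, of which Bst2 lost 199, although the blood cell genes Mpeg1 (5.33 to 1.87 CPM) and Fyb (5.90 to 2.26 CPM) fell as well. The ribosome biogenesis median was 0.184 with the covariate, 41.5% of its size, so that the axis may account for most of that pattern, although 19 of 24 members were then called higher. What the axis stands for, such as culture density or handling, was not tested. Library scores on it were not centred within groups, and their means were −0.424 ± 0.78 at 37 °C and 0.412 ± 1.24 at 44 °C. The covariate can therefore also take out a temperature effect along the axis. The fall of both medians cannot tell the axis from temperature, which stays open for the whole of both patterns.

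Genes that changed at 44 °C tended to have the same sign at 40 °C. Over the 6 ways of giving different 37 °C libraries to the 2 comparisons, the median signed log2 fold change at 40 °C of genes called at 44 °C lay between 0.0397 and 0.0834, with 71.2% to 79.5% of genes of the same sign, as a partial shift at 40 °C would give. With the within-group axis as a covariate, where 1731 to 2195 genes were called at 44 °C in place of 369 to 1521, the medians were 0.0393 to 0.0512 and 65.5% to 74.3% had the same sign, which argues against the axis as the whole cause but leaves room for it as a part. In regroupings of the 12 libraries, 14 of 100 gave a covariance between the comparisons as large as the real one (0.0396, highest other 0.0731), so chance cannot be excluded and the partial shift stays a hypothesis.

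Other splits of the same libraries show how often a regrouping gives counts as large as the real ones. For 44 °C against 37 °C, 1 of 35 splits, the real one, called as many genes (1658 with the 8 libraries alone, highest other 1258). This is the smallest share that 35 splits can give. In 2 of 100 regroupings of the 12 libraries as many genes differed among the 3 temperatures (1184, highest other 1710), the real one included, so a random regrouping exceeded the real count. Both shares argue against chance, but so few splits do not exclude it. For 40 °C against 37 °C the real count of 0 fixed the outcome, since all 35 splits call at least 0 genes (highest other 1), so this count decides nothing. For 44 °C against 40 °C, 2 of 35 splits called as many, the real one included (334, highest other 2058). This share does not argue against chance, although 31 of the other splits called no gene. The split with 2058 is taken up below. For the number of gene lists called, chance cannot be excluded in any of the 3 comparisons. As large a number came from 21 of 35 splits for 40 °C against 37 °C (6 lists, highest other 22), 9 of 35 for 44 °C against 37 °C (11, highest other 18) and 16 of 35 for 44 °C against 40 °C (9, highest other 21).

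The split that called 2058 genes exchanged 40 °C replicate 2 with 44 °C replicate 1, which points to a structure of the samples, and exchanged labels were tested by the place of each library between the other 40 °C libraries (0) and the other 44 °C libraries (1). The way of testing was changed 2 times after values were seen: the first measure, a median over 2578 genes, placed 44 °C replicate 1 at 0.329 and 40 °C replicate 2 at 0.584, as an exchange would, and was set aside because those genes followed the within-group axis built without them (r = 0.983, permutation p = 0.000217, and r = 0.997 without both libraries), on which the 2 lie at −1.07 and 1.46. The ER genes did not pass the test for following it (r = −0.330, permutation p = 0.333), which does not show that they are free of it. They placed the 2 libraries at 0.998 and 0.164, where the other 44 °C libraries lay at 0.936 to 1.06 and the other 40 °C libraries at −0.021 to 0.0261. The range of the other libraries, the first bound used on this measure, left the question undecided because of the 0.164, and the midpoint was then used as the bound. By the midpoint the 2 libraries lay on the side of their labels, which argues against an exchange, though by a bound chosen after values were seen. Hspb1 was at 251.6 CPM in 44 °C replicate 1 and 61.1 in 40 °C replicate 2. It was named by a rule that asks for no overlap between the groups as labelled, so its values cannot decide the question. Hspa5, itself a member of the ER list, was at 974 and 1968 CPM.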

How the results depend on the processing

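The within-group axis as a covariate was added after seeing the data, and every other alternative here was planned. The list calls at 40 °C, the count of genes at 44 °C against 40 °C and the sizes of all counts were the least stable results, and the cause was not tested except where an alternative tests fewer samples. For 40 °C against 37 °C the count of 0 genes became 13 with no filter on low counts (3 higher, 10 lower), 11 with the axis and 4 with DESeq2, and 0 to 1 with a library left out (1 without 44 °C replicate 1). For 44 °C against 37 °C the count of 1975 became 3146 with the axis and 630 at a threshold of 0.01, and 979 (without 37 °C replicate 1) to 3355 (without 44 °C replicate 1) with a library left out. It was also 1156 without 37 °C replicate 2, 1063 without 37 °C replicate 4, 980 without 44 °C replicate 2 and 1062 without 44 °C replicate 4. DESeq2 (2674), limma voom (2015), library totals (2008) and the 8 libraries alone (1658) stayed within 1.5 times. For 44 °C against 40 °C the count of 724 became 2535 with the axis, 334 with the 8 libraries alone, 1220 with DESeq2 and 270 at a threshold of 0.01, and 394 (without 40 °C replicate 1) to 1265 (without 44 °C replicate 1) with a library left out. It was also 421 without 40 °C replicate 3, 420 without 40 °C replicate 4, 426 without 44 °C replicate 2 and 456 without 44 °C replicate 4. Library totals gave 751 with 52.7% higher, against 37.4% with TMM.

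The 4 lists called for 40 °C against 37 °C became 0 with an estimated correlation and 0 with fry, and 2 to 10 with a library left out (2 without 40 °C replicate 2, 9 without 37 °C replicate 3, 9 without 40 °C replicate 3, 10 without 40 °C replicate 4). With an estimated correlation the 11 lists for 44 °C against 37 °C became 1 and the 10 for 44 °C against 40 °C became 1. Fry called 9 and 7 lists. For 44 °C against 37 °C it called ER, interferon (fry adjusted p = 0.0267), NF-kB (0.00895), NRF2 (5.81e-05), circadian (0.0286) and DNA replication genes (0.0456). It did not call ribosome biogenesis (0.135), fibrillar matrix (0.113), cholesterol (0.113), TRiC (0.157) or glycolysis genes (0.221). For 44 °C against 40 °C it called, of the lists passing camera, ER, interferon, NF-kB, NRF2 and smooth muscle genes (at most 0.0473). With a library left out the lists called by camera numbered 10 to 16 and 6 to 13 (6 without 40 °C replicate 4). Of the lists not called, 10 of 33, 7 of 26 and 5 of 27 in the 3 comparisons were called under at least 1 of up to 16 camera refits at the preset correlation. Apart from these refits, fry called metallothionein (adjusted p = 0.00188), endothelial (0.00141) and smooth muscle genes (0.0386) for 44 °C against 37 °C. For 44 °C against 40 °C fry called metallothionein (0.0335) and endothelial genes (0.036), which camera had not called. The covariance of 0.0396 became 0.0205 with at least 5 CPM in 4 libraries, and 0.035 to 0.0598 with a library left out (highest without 37 °C replicate 3). It was 0.0194 with the 37 °C libraries divided, which by design takes out the part that shared libraries give. Genes called at both temperatures numbered 0 to 1 with a library left out (1 without 44 °C replicate 1). The 1184 genes differing among the 3 temperatures became 1784 with no filter, 3009 with the axis, and 562 (without 44 °C replicate 2) to 2125 (without 44 °C replicate 1) with a library left out. They were also 742, 698 and 678 without 37 °C replicates 1, 2 and 4, and 725 and 609 without 44 °C replicates 3 and 4.

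With a library left out, 48.3% (without 37 °C replicate 1) to 99.9% (without 40 °C replicate 2) of the 1975 genes called for 44 °C against 37 °C stayed called. For the 724 genes of 44 °C against 40 °C it was 53.2% (without 40 °C replicate 1) to 94.2% (without 37 °C replicate 1). Named genes were in part picked for large changes or small p, and none was called at 40 °C against 37 °C, so their values overstate this stability. Of values of named genes under alternatives, 665 of 677 kept their direction and side of the threshold for 40 °C against 37 °C, 904 of 939 for 44 °C against 37 °C and 884 of 895 for 44 °C against 40 °C. The sign was reversed in 12, 15 and 5 cases, and 1 of them was called, Hsph1 for 44 °C against 37 °C with the axis, at −0.234 (adjusted p = 0.00123, range over its alternatives 0.00123 to 1). The others were not called before or after, at 0.167 or less in size. With the axis Sox9 was at 0.0459, 0.0863 and 0.0404 in the 3 comparisons, in the order above. Runx2 was at −0.00849 for 40 °C against 37 °C with library totals. Hsph1 for 44 °C against 37 °C was at −0.00947 with at least 5 CPM in 4 libraries, −0.000624 with the 8 libraries alone and −0.00999 with limma voom. With a library left out, values for 40 °C against 37 °C crossed 0 in Fos (−0.0621 to 0.0999), Cdkn1a (−0.146 to 0.165), Sox9 (−0.184 to 0.0540) and Runx2 (−0.0176 to 0.0387). For 44 °C against 37 °C they did in Hsph1 (−0.103 to 0.145), Dnajb1 (−0.00240 to 0.0604), Atf3 (−0.00950 to 0.258) and Col2a1 (−0.160 to 0.168), and for 44 °C against 40 °C in Cirbp (−0.0218 to 0.239), Sox9 (−0.300 to 0.0451) and Acan (−0.389 to 0.167). A call was lost in 13 cases, all with a library left out and all for 44 °C against 37 °C, in Zfp566, Utp4, Nop14 and Rrp9. Zfp566 lost it without 37 °C replicate 2 (0.0515) and 44 °C replicate 4 (0.0564, range over its alternatives 0.00126 to 0.0564), Nop14 without 37 °C replicates 1, 2 and 4 and 44 °C replicates 2 and 4 (adjusted p 0.0713 to 0.0938), and Rrp9 without 37 °C replicates 1 and 4 and 44 °C replicates 2 and 4 (0.0714 to 0.0943). At this depth, genes below about 1 CPM, such as Hspa1a at 37 °C, rest on few reads.

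The replicate numbers shared between groups did not meet the rule for pairing, that every same-number pair correlates above 0.1, since 3 of 12 did (−0.207 to 0.366). That 6 of 12 libraries correlated best with their own number is a hint from the data, so that some sharing stays open. With the number as a block, 0, 2557 and 901 genes were called in the 3 comparisons, 5, 12 and 10 lists (added were NF-kB genes for 40C vs 37C, adjusted p = 0.0265, range over its alternatives 0.0147 to 0.385, and endothelial genes for 44C vs 37C, adjusted p = 0.0492, range 0.0415 to 0.13), 1656 genes differed among the temperatures, and the covariance was 0.0398. Of the named genes it changed the call of Hspa8 for 44 °C against 40 °C (−0.28, adjusted p = 0.0465, range over its alternatives 7.32e-08 to 0.256) and the sign of the uncalled Hsph1 for 44 °C against 37 °C (−0.00669).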

Other observations

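The gene lists below were fixed beforehand and did not pass camera in any comparison with the settings of the report, although some passed under alternatives, and the genes named from them were chosen after their values were seen. Mitosis genes went both ways at 44 °C against 37 °C. Of 28 measured, Top2a (DNA topoisomerase, 1509 ± 41.9 to 1818 ± 67.9 CPM, log2 fold change 0.27) and the mitotic kinase gene Cdk1 (0.29) rose. The cyclin gene Ccnb2 (−0.37), the anaphase activator gene Cdc20 (−0.36, from 359.6 ± 29.6 to 281 ± 26.3 CPM), the spindle checkpoint gene Bub1b (−0.21), the phosphatase gene Cdc25c (−0.40) and the securin gene Pttg1 (−0.28) fell. Adjusted over the list alone 4 rose and 5 fell. The list's camera adjusted p was 0.986 with a median of 0.01, a mean of −0.03 and a direction of lower. Fry for change in either direction called 25 of the 37 lists in that comparison, this one at an adjusted p of 2.98e-09. DNA replication genes, in contrast, had 9 of 28 higher and none lower.

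The metallothionein gene Mt2, which encodes a metal-binding stress protein, had 65.5 ± 11.7 CPM at 37 °C, 41.5 ± 4.10 at 40 °C and 26.2 ± 4.95 at 44 °C (n = 4 each). It fell at 44 °C against 37 °C (log2 fold change −1.32, adjusted p = 7.66e-05) and against 40 °C (−0.66, adjusted p = 0.0139). It was not called at 40 °C against 37 °C by edgeR (−0.66, adjusted p = 0.823), although its libraries did not overlap. Mt1 fell at 44 °C (−0.51), the other called member of 6, and 1 gene rose and 2 fell adjusted over the list alone (camera adjusted p = 0.273). Fry called the metallothionein list lower at 44 °C against 37 °C (adjusted p = 0.00188) and against 40 °C (0.0335). Malat1, a nuclear-retained RNA, had 956 ± 140.5 CPM at 37 °C, 657 ± 105 at 40 °C and 753 ± 41.1 at 44 °C, and Neat1 had 269.8 ± 30.2, 210.0 ± 19.6 and 202 ± 11.8 CPM. Both fell at 44 °C against 37 °C (−0.34 and −0.42, adjusted p = 0.049 and 0.00437), as did 2900097C17Rik, while Gas5 rose (0.58), of 12 noncoding RNAs, with 1 rising and 3 falling adjusted over the list alone (list adjusted p = 0.986). For 40 °C against 37 °C that list passed under 3 of 16 alternatives (lowest adjusted p = 0.000227).

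TGF-beta and BMP response genes also divided at 44 °C against 37 °C. Of 19, Ctgf rose while the inhibitors of differentiation Id1, Id3 (−0.56) and Id4 (−0.50), the matrix gene Tgfbi (−0.76) and Ltbp2 (−0.37) fell, and 2 rose and 5 fell adjusted over the list alone (list adjusted p = 0.29). Of 29 immediate early genes, Cyr61, Dusp5 (0.76), Nr4a1 (0.24) and Srf (0.30) rose and Junb (−0.29), Klf2 (−0.67) and Klf4 (−0.23) fell, with 4 and 3 adjusted over the list alone (list adjusted p = 0.294). Of 19 p53 target genes 5 rose and 3 fell, with 6 and 5 adjusted over the list alone (list adjusted p = 0.986), among them the nuclease gene Aen (0.67) and the death receptor gene Fas (−0.78). ATF4 stress genes had 3 higher and 3 lower of 25, with 4 and 3 adjusted over the list alone (list adjusted p = 0.975), including Atf4 itself (0.35) and Slc7a11 (−0.83). Autophagy and lysosome genes had 1 higher, Wipi2, and 5 lower of 20, with 2 and 7 adjusted over the list alone (list adjusted p = 0.105). This list passed under 5 of 16 alternatives for 40 °C against 37 °C (lowest adjusted p = 0.00831) and 2 of 16 for 44 °C against 37 °C (0.0367).

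None of 25 oxidative phosphorylation, 12 mitochondrially encoded or 38 cytosolic ribosomal protein genes was called at 44 °C against 37 °C by edgeR over all genes or adjusted over the list alone (list adjusted p = 0.925, 0.226 and 0.77). The mitochondrially encoded list passed under 2 of 16 alternatives in that comparison (lowest adjusted p = 0.000422). Of the 8 histone genes Hist1h1c fell (−1.13, list adjusted p = 0.226). Of 20 SR protein and CLK kinase genes Hnrnpa1 rose (0.45, list adjusted p = 0.297) and of 13 ion channel genes Stim1 rose (0.35, list adjusted p = 0.993), each alike adjusted over the list alone. Of 27 proteasome genes Psma7 (−0.15) and Nfe2l1 (−0.18) fell, or 1 adjusted over the list alone (list adjusted p = 0.273). Of 21 apoptosis genes Cycs rose (0.35) and Bcl2l1 (−0.19) and Bcl2l11 (−0.28) fell. Of 10 Wnt response genes Tcf7 rose (0.29) and Notum (−0.66) and Ccnd1 (−0.23) fell, with 1 rising and 2 falling in each adjusted over the lists alone (list adjusted p = 0.273 and 0.986). Sox2, a transcription factor gene of the pluripotent list, had 92.8 ± 3.36 CPM at 37 °C and 93.5 ± 5.12 at 44 °C (0.01, adjusted p = 0.939).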
